A study of Mus musculus with 6 samples.

How the data were processed

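The data are crosslinking and immunoprecipitation with sequencing (CLIP-seq) libraries of polypyrimidine tract binding proteins in mouse cortex. PTBP1 and PTBP2 are related RNA-binding proteins that bind pyrimidine-rich RNA and regulate splicing; PTBP1 is low in neurons, and PTBP2 is the form present in developing neurons. Per the labels' protocols, cortices were taken on postnatal day 1, irradiated with ultraviolet light at 400 mJ/cm2 to crosslink proteins to RNA, and nuclear fractions were immunoprecipitated. RNA bound to the beads was trimmed with micrococcal nuclease, complexes were separated by size, and the membrane between 80 and 110 kDa was taken, above the 60 kDa of FLAG-PTBP1 and the 58 kDa of PTBP2. The RNA was then copied to cDNA, circularised, amplified and sequenced. Rosa-PTBP1 is a transgene expressing FLAG-tagged PTBP1, and Emx1-cre is a recombinase driver active in the dorsal forebrain, including the progenitors of cortical excitatory neurons. PTBP2 loxP alleles are alleles that this recombinase can delete.

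The 6 libraries fall into 5 groups by their labels. FLAG antibody was used in wild-type cortex (2 libraries, replicates 1 and 2), in Rosa-PTBP1 cortex (1 library) and in Rosa-PTBP1 cortex that was also homozygous for PTBP2 loxP alleles (1 library). PTBP2 antibody was used in wild-type cortex (1 library) and in Rosa-PTBP1 cortex (1 library). All Rosa-PTBP1 cortex carried Emx1-cre, so a comparison with wild type differs by the transgene and the recombinase together. Wild-type cortex carries no FLAG-PTBP1, so its FLAG libraries measure the background of the antibody and procedure. The labels do not say whether the replicates came from separate animals.

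The reads were aligned with Bowtie to the mm9 mouse genome, per the submitters' processing notes; the Bowtie version is not given in the sources used here. Each deposited list holds read intervals of clusters that passed a false discovery rate, per the file headers; the caller, its level and its background are not given in the sources used here. Each line gives a chromosome, start, end, strand and read name, and no score, count or gene name. An interval can be listed on several lines with the same read name, and the meaning of these repeats is not stated. Lines were therefore collapsed to distinct intervals, meaning unique combinations of chromosome, strand, start and end. Distinct intervals of 1 strand that overlapped or touched were merged into sites. A stacked site is a site built from 5 or more distinct intervals, a definition chosen after the data were seen. Because the lists hold significant clusters only, a region listed at 0 sites may still have held reads, and no fold is given for it.

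No gene model of mm9 was used here, so no site was assigned to a gene, exon, intron or untranslated region. The annotation at hand was of the GRCm38 build: the lists reach position 152445632 on chromosome 7, where that annotation ends at 145324086, and coordinates were not converted. The rule for regions named in the text, fixed before the data were examined, therefore used 100-kb windows, written here in Mb of mm9, in place of genes. For each comparison it takes, among windows with 20 or more sites in both libraries together, the 10 highest and 10 lowest log2 ratios whose 95% interval excludes the library-wide ratio, and for each library the 10 windows with most sites. The 12 gene lists fixed in advance (233 genes) and the motif and place of sites were not analysed here for the same reason. Other choices listed as alternatives were also fixed before the data were examined, apart from those named as added.

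Some chromosomes were nearly empty in 1 library. A chromosome was called sparse in a library when its share of that library's sites was below 0.5 times the median share in the other libraries, a rule added after the data were seen. Named windows of the loxP, transgene and antibody comparisons were then taken on chromosomes that were filled in both libraries compared. The windows with most sites per library, and those higher than the wild-type FLAG libraries, were taken on all chromosomes.

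Overlap between libraries was counted as the share of sites with at least 1 base of overlap on the same strand, with an exact Clopper-Pearson 95% interval. For overlaps among stacked sites, both libraries were cut to their stacked sites. The chance level came from the same sites moved at random by 500 to 5000 bases in either direction, averaged over 100 draws. In the depth-matched comparison each library was drawn down to 51141 distinct intervals on the 12 chromosomes filled in all libraries; the FLAG library of wild-type replicate 2, which holds fewer, was left out. For each window the log2 ratio of the shares of sites was computed with a pseudocount of 0.5, with an exact conditional binomial 95% interval. Folds given in the text are ratios of the shares without a pseudocount. Apart from the FLAG wild-type pair each group holds 1 library; no significance test between conditions was run, and no p-values are given. The hypotheses in the closing section are described with bootstrap intervals over sites, which cover only these libraries. Intervals cover counting error only, not differences between animals or library preparations, and sites near each other are not independent. Distinct intervals within 1 site are not independent either, so 95% intervals for windows counted from them are too narrow.

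Read names give the sequencing run. The FLAG libraries of Rosa-PTBP1, of Rosa-PTBP1 with loxP alleles and of wild-type replicate 2 came from 1 run, named WA047. The FLAG library of wild-type replicate 1 and both PTBP2 libraries came from a pair of other runs, named XA041 and XB028. The FLAG libraries of Rosa-PTBP1 cortex, with or without loxP alleles, therefore cannot be told apart from PTBP2 by antibody alone, since the run differs too. The PTBP2 libraries were compared within each run as well as pooled.

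The window comparison was tested on simulated data drawn from the pooled window shares at the real library sizes. In the loxP simulation 200 windows were changed 4-fold, and 95.4% of the 175 changed windows that were measured were recovered; 6.30% of 651 unchanged windows lay outside. In the transgene simulation 163 windows were changed 4-fold, with 96.3% of 135 recovered and 6.22% of 193 unchanged windows outside. In the antibody simulation 200 were changed 4-fold, with 99.3% of 146 recovered and 6.57% of 396 unchanged windows outside. Sites were drawn independently and apart from the changed windows both simulated libraries had the same profile. The shares of unchanged windows outside therefore cover counting error only, not differences between real libraries. Alternatives changed the overlap rule, the site width, the merging distance, the windows and chromosomes used, the library size, the background filter, the minimum of sites per window, the weight of a site and the pseudocount. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.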

Results

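CLIP-seq libraries of FLAG-PTBP1 and PTBP2 from mouse cortex on postnatal day 1 were compared to ask where each protein was crosslinked to nuclear RNA, how much of the FLAG signal was background, and whether the sites of each protein differed when the other was altered. The series held 2 FLAG libraries from wild-type cortex, 1 from Rosa-PTBP1 cortex, 1 from Rosa-PTBP1 cortex homozygous for PTBP2 loxP alleles, and 1 PTBP2 library each from wild-type and Rosa-PTBP1 cortex. Rosa-PTBP1 cortex also carried Emx1-cre, so comparisons with wild type differ by both. Apart from the wild-type FLAG pair there were no replicates.

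A window on chromosome 2 from 6.7 to 6.8 Mb, with all its sites on the minus strand, held the most sites of any 100-kb window in each of the 6 libraries. It held 204 sites in FLAG Rosa-PTBP1, 187 in FLAG with loxP alleles, 194 in PTBP2 wild type and 156 in PTBP2 Rosa-PTBP1, and 163 and 89 in the wild-type FLAG replicates 1 and 2. Per 1000 sites this was 4.74 in FLAG Rosa-PTBP1, 7.06 in PTBP2 wild type, 2.22 in wild-type FLAG replicate 1 and 9.30 in replicate 2. A background library thus held the window at a higher share of sites than FLAG-PTBP1 did. From distinct intervals this was not seen: the window held 8076 of 351602 in FLAG Rosa-PTBP1 and 557 of 26665 in replicate 2. Other site-rich windows of the FLAG-PTBP1 library lay on chromosome 11 from 36.4 to 36.5 Mb (181 sites), chromosome 16 from 6.8 to 6.9 Mb (177 sites) and chromosome 1 from 170.3 to 170.4 Mb (175 sites). The PTBP2 wild-type library held 114 sites on chromosome 14 from 40.1 to 40.2 Mb and 105 on chromosome 1 from 3.5 to 3.6 Mb. Of the 10 windows with most sites, FLAG Rosa-PTBP1 shared 8 with the FLAG loxP library, 5 with PTBP2 wild type, 3 with PTBP2 Rosa-PTBP1 and 4 with each wild-type FLAG library. These windows were taken on all chromosomes, so sparse chromosomes lower the sharing. Those of FLAG Rosa-PTBP1 on chromosome 9 from 27.6 to 27.7 and 27.9 to 28 Mb were listed at 0 in PTBP2 Rosa-PTBP1. That of the loxP library on chromosome 10 from 69.1 to 69.2 Mb was listed at 0 in FLAG Rosa-PTBP1.

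Regions obtained by merging the intervals of all 6 libraries differed in how far they were shared with the background. The 3 below were chosen after their values were seen, and counts are the intervals of each library inside the region. On chromosome 19, the minus-strand region from 5797121 to 5798137 held 1788 distinct intervals in FLAG Rosa-PTBP1 (0.509% of its intervals), 851 in PTBP2 wild type (0.547%), 129 in wild-type FLAG replicate 1 (0.146%) and 1434 in replicate 2 (5.38%). The background libraries thus lay on opposite sides of FLAG-PTBP1. On chromosome X, the minus-strand region from 100661940 to 100663380 held 1482 intervals in FLAG Rosa-PTBP1, 1697 in FLAG with loxP alleles, 1708 in PTBP2 wild type and 1595 in PTBP2 Rosa-PTBP1, against 2 and 9 in the wild-type FLAG replicates. As shares of all intervals these were 0.421%, 0.638%, 1.10% and 2.14%, against 0.00226% and 0.0338%. PTBP2 Rosa-PTBP1 was sparse on 7 chromosomes, X among them, which raises its 2.14% against the other libraries. The surrounding window from 100.6 to 100.7 Mb was not low in replicate 2. It held 217 intervals and 14 sites there, against 1748 and 15 in FLAG Rosa-PTBP1. By share of sites this window was lower in FLAG Rosa-PTBP1 than in replicate 2 (log2 -2.07, -3.22 to -0.91). On chromosome 2, the region from 6779052 to 6782806 held 1520 intervals in FLAG Rosa-PTBP1 (0.432%) against 27 (0.0306%) and 82 (0.308%) in wild-type FLAG replicates 1 and 2.

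The depth of the libraries depended on what was counted. FLAG wild-type replicate 1 listed 376546 lines and FLAG Rosa-PTBP1 373469, but these came from 88327 and 351602 distinct intervals, or 4.26 and 1.06 lines per interval. FLAG with loxP alleles held 265953 distinct intervals, PTBP2 wild type 155447, PTBP2 Rosa-PTBP1 74416 and FLAG wild-type replicate 2 26665. Merged sites numbered 73519, 9567, 43026, 34912, 27469 and 22637 in FLAG wild-type replicates 1 and 2, FLAG Rosa-PTBP1, FLAG with loxP alleles, PTBP2 wild type and PTBP2 Rosa-PTBP1. Sites of 5 or more distinct intervals numbered 402, 857, 24241, 17571, 9652 and 2960 in the same order. Sites of a single interval made up 85.8% of the sites of wild-type replicate 1 and 15.1% of those of FLAG Rosa-PTBP1.

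**Figure D1:**
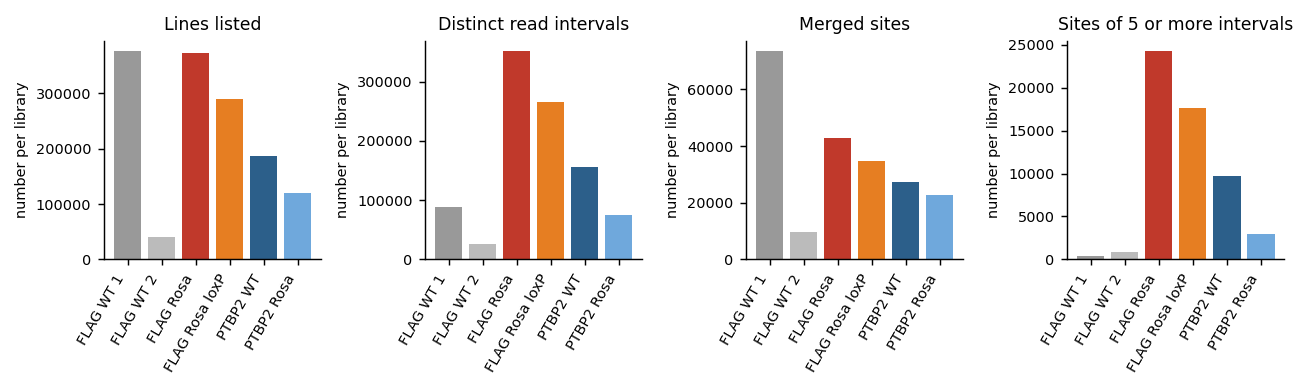
Bars show, for each of the 6 libraries, the number of lines, distinct read intervals, merged sites and sites of 5 or more intervals. FLAG wild-type replicate 1 has the most lines (376546) and merged sites (73519) but 402 sites of 5 or more intervals, against 24241 in FLAG Rosa-PTBP1.

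Chromosomes were unevenly filled. FLAG Rosa-PTBP1 held few sites on chromosome 10, and PTBP2 Rosa-PTBP1 held few on chromosomes 4, 5, 6, 7, 8, 9 and X. On chromosome 4 the PTBP2 Rosa-PTBP1 library held 550 sites before 60 Mb against 396 in PTBP2 wild type, and 107 against 1213 after it. Differences on these chromosomes are therefore not described as differences between genotypes. The rule screens whole chromosomes only. PTBP2 Rosa-PTBP1 kept 51 sites on sparse chromosome 9 from 49.5 to 49.6 Mb, and stretches missing from filled chromosomes were not screened out.

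**Figure D2:**
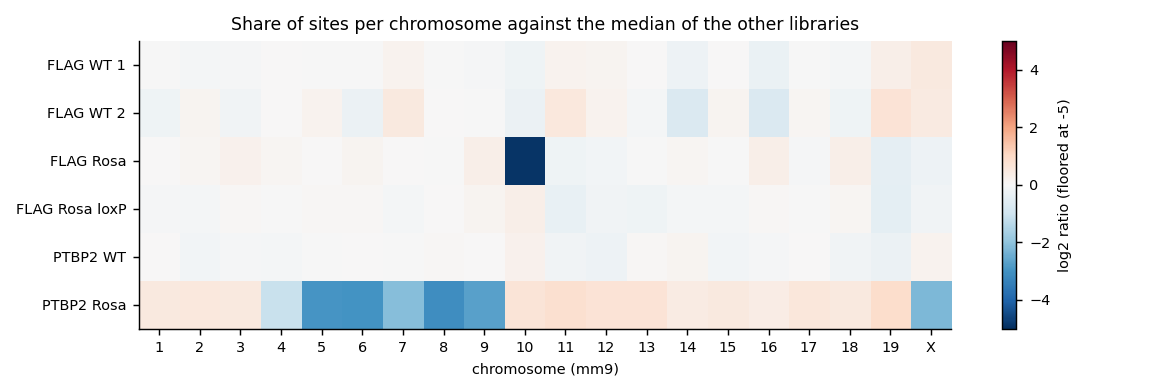
Colours show, for each library (rows) and chromosome (columns, mm9), the log2 ratio of its share of sites to the median share in the other libraries, floored at -5. FLAG Rosa-PTBP1 is nearly empty on chromosome 10, and PTBP2 Rosa-PTBP1 is low on chromosomes 4 to 9 and X.

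FLAG-PTBP1 sites were set against the wild-type FLAG libraries to measure the background. Against replicate 1 the highest window lay on chromosome 7 from 85.7 to 85.8 Mb, with 19 sites against 1, a share 32.5-fold higher (95% interval 5.16 to 1349), followed by chromosome 13 from 28.6 to 28.7 Mb, with 23 against 2 (19.7-fold, 4.86 to 172). Against replicate 2 the highest lay on chromosome 9 from 27.9 to 28 Mb (166 sites), chromosome 2 from 4.1 to 4.2 Mb (139) and chromosome 1 from 3.5 to 3.6 Mb (135), each listed at 0 in that replicate. The next windows come from those above both replicates, ordered by the lower of the 2 ratios, an order chosen apart from the rule for named windows. The window on chromosome 15 from 66.1 to 66.2 Mb held 31 sites in FLAG Rosa-PTBP1 against 4 in wild-type replicate 1, a share 13.2-fold higher (4.68 to 51.6), and was listed at 0 in replicate 2. On chromosome 18 from 79.2 to 79.3 Mb there were 123 sites against 29 and 3, shares 7.25-fold (4.80 to 11.3) and 9.12-fold (3.05 to 44.8) higher. The chromosome 9 window held 41 sites in replicate 1, a share 6.92-fold higher in FLAG Rosa-PTBP1 (4.89 to 9.99). Windows on chromosome 8 from 75.5 to 75.6 Mb (75 sites against 13 and 0) and chromosome 14 from 35.8 to 35.9 Mb (51 against 12 and 0) were also among the first 10 in this order. In all, 335 of 562 windows lay above both wild-type libraries. These 562 hold 20 or more sites in FLAG Rosa-PTBP1 together with each wild-type library, and since replicate 2 has few sites, this favours windows rich in FLAG Rosa-PTBP1 sites. Against replicate 1 alone 493 of 1333 windows were higher and 124 lower, and against replicate 2 alone 376 of 562 were higher and 7 lower. The lowest against replicate 1 on filled chromosomes lay on chromosome 6 from 63.5 to 63.6 Mb (listed at 0 against 26 sites) and chromosome 12 from 45.6 to 45.7 Mb (listed at 0 against 23). The 7 lower than replicate 2 by share of sites included chromosome 19 from 5.7 to 5.8 Mb, with 11 sites against 13 (log2 -2.47, -3.78 to -1.21 on filled chromosomes), and the window on chromosome 2 from 6.7 to 6.8 Mb (log2 -1.05, -1.41 to -0.67). Of the FLAG Rosa-PTBP1 sites, 7.94% (7.69 to 8.20) overlapped a site of either wild-type library, where shifted sites gave 3.94%; with the larger library thinned it was 4.20%, and within 50 bases 12%. The overlap was 6.38% with replicate 1 alone and 1.98% with replicate 2 alone, so replicate 1 decides much of this value. Of the stacked FLAG Rosa-PTBP1 sites on filled chromosomes, 1.60% (1.45 to 1.77) overlapped a stacked site of the merged wild-type libraries, against 0.384% for shifted sites. The wild-type libraries held only 402 and 857 stacked sites, so this share was bound to be low and is not read as less background.

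The wild-type FLAG replicates were compared with each other. Of the sites of replicate 2, 3.84% (3.46 to 4.24) overlapped a site of replicate 1, against 1.64% for shifted sites. With the larger library thinned it was 0.512% (0.379 to 0.677), and within 50 bases 5.93%. Across 711 windows the Spearman correlation of their site numbers was -0.04, computed across windows, which are not independent. Replicate 2 overlapped FLAG Rosa-PTBP1 more, at 9.17% (8.60 to 9.76) against 2.22% for shifted sites. Of its stacked sites on filled chromosomes, 43.2% (39.8 to 46.7) overlapped a stacked FLAG Rosa-PTBP1 site, against 10.7% for shifted sites. These libraries came from different sequencing runs, replicate 2 from that of FLAG Rosa-PTBP1. Of the distinct intervals of replicate 2, 5.51% were identical to one of FLAG Rosa-PTBP1, 3.02% to one of PTBP2 wild type and 0.566% to one of replicate 1. For PTBP2 Rosa-PTBP1, from other runs, it was 2.05%. These 4 libraries differed in depth, with 351602, 155447, 88327 and 74416 distinct intervals in the same order. The shares are not scaled for depth, so they do not show more identity within the run. Shared background and reads crossing over within the run cannot be told apart here.

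FLAG-PTBP1 was then compared with and without the PTBP2 loxP alleles, which asks whether its sites differ where PTBP2 can be deleted. On chromosome 1 from 125.5 to 125.6 Mb the loxP library held 24 sites against 8, a share 3.94-fold higher (1.71 to 10.1). On chromosome 6 from 80.2 to 80.3 Mb it held 31 against 11, 3.70-fold higher (1.81 to 8.16), and on chromosome 17 from 86.9 to 87 Mb 24 against 9, 3.50-fold higher (1.57 to 8.56). In the other direction, chromosome 5 from 122.4 to 122.5 Mb held 3 sites with loxP alleles against 38 without, a share 9.65-fold lower (3.06 to 48.9). Chromosome 18 from 42.9 to 43 Mb held 3 against 36, 9.14-fold lower (2.89 to 46.4), and chromosome 14 from 36.1 to 36.2 Mb 3 against 32, 8.13-fold lower (2.54 to 41.5). In each of these windows the higher FLAG-PTBP1 share lay above both wild-type FLAG libraries. Except on chromosome 1, the lower share fell below at least 1 of them. Per 1000 sites, FLAG Rosa-PTBP1 held 0.256 on chromosome 6 and the loxP library 0.0859 on chromosome 18, against 0.286 and 0.381 in replicate 1. The 10 highest windows ranged from 2.63-fold to 3.94-fold, and the 10 lowest from 4.32-fold to 9.65-fold, on chromosomes filled in both. Of 839 windows there, 42 were higher and 79 lower with loxP alleles, and the Spearman correlation across windows was 0.72. Of the loxP library's sites, 44.5% (44.0 to 45.0) overlapped a FLAG Rosa-PTBP1 site, against 10.1% for shifted sites. Of its stacked sites on filled chromosomes, 58.9% (58.1 to 59.7) overlapped a stacked FLAG Rosa-PTBP1 site, against 12.7% for shifted sites. With chromosome 10 kept, each of the 10 highest windows lay on it. With all chromosomes, 53 windows were higher and 94 lower from sites, and 219 higher and 357 lower from distinct intervals. Distinct intervals of 1 site are not independent, so counts from them put too many windows outside. Both libraries came from 1 run, with 1 library each, so how far replicates would differ is unknown. Between the wild-type FLAG replicates, which differed in run and depth, 11.5% of 711 windows lay outside the library-wide ratio. The loxP comparison had 14.4% of 839 outside on filled chromosomes, so its windows are not shown to exceed differences between replicates.

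PTBP2 was compared with and without the Rosa-PTBP1 transgene, which asks whether PTBP2 sites differ where FLAG-PTBP1 is also present. On chromosome 13 from 46 to 46.1 Mb, PTBP2 wild type held 25 sites and the Rosa-PTBP1 library was listed at 0. The same held on chromosome 18 from 40.4 to 40.5 Mb (25 sites) and chromosome 10 from 89.3 to 89.4 Mb (24 sites). Nearby on chromosome 13, windows from 45.7 to 45.8 and 45.9 to 46 Mb were also listed at 0, against 9 and 19 sites in PTBP2 wild type. A missing stretch of the list therefore cannot be told apart from a difference there. On chromosome 10 from 32 to 32.1 Mb the Rosa-PTBP1 library held 2 sites against 44, a share 26.3-fold lower (6.86 to 224). On chromosome 14 from 19.6 to 19.7 Mb it held 3 against 36, 14.3-fold lower (4.53 to 72.8), and on chromosome 3 from 73.1 to 73.2 Mb 4 against 46, 13.7-fold lower (5.02 to 52.6). The single window that was higher on filled chromosomes lay on chromosome 14 from 117.3 to 117.4 Mb, with 17 sites against 5 (2.85-fold, 1.01 to 9.86). In the transgene simulation 6.22% of unchanged windows lay outside from counting error alone, so this window is not shown to exceed such error. Of 279 windows on filled chromosomes, 1 was higher and 121 lower, with a Spearman correlation of 0.60 across windows. Sites of a single interval made up 46.2% of all PTBP2 Rosa-PTBP1 sites and 23.9% of all PTBP2 wild-type sites. With distinct intervals counted in place of sites on all chromosomes, 85 windows were higher and 145 lower, where sites gave 5 and 113. Distinct intervals of 1 site are not independent, so counts from them put too many windows outside. Of the PTBP2 Rosa-PTBP1 sites, 17.6% (17.1 to 18.1) overlapped a PTBP2 wild-type site, against 3.13% for shifted sites. The 2 libraries mixed their sequencing runs differently, with 30.3% of PTBP2 wild-type intervals and 61.0% of PTBP2 Rosa-PTBP1 intervals from XA041. Within single runs the overlap was 15.6% in XA041 and 33.1% in XB028. Windows on filled chromosomes numbered 0 higher and 110 lower of 234 in XA041, and 1 higher and 32 lower of 227 in XB028. Of the stacked PTBP2 Rosa-PTBP1 sites on filled chromosomes, 64.3% (62.4 to 66.0) overlapped a stacked PTBP2 wild-type site, against 9.15% for shifted sites. In the other direction, from the library with more stacked sites, it was 27.0% (25.9 to 28.1) against 3.91%.

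**Figure D3:**
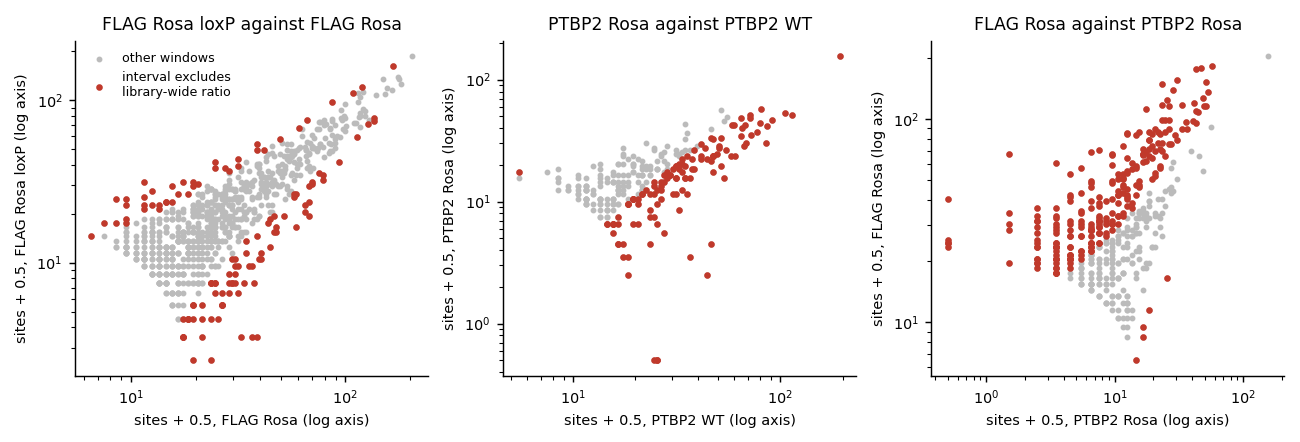
Points are 100-kb windows with 20 or more sites on chromosomes filled in both libraries; both axes are the number of sites plus 0.5 on log scales, and red marks windows whose 95% interval excludes the library-wide ratio. Red windows number 42 higher and 79 lower with loxP alleles, 1 higher and 121 lower for PTBP2 with Rosa-PTBP1, and 242 higher and 5 lower for FLAG-PTBP1 against PTBP2.

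FLAG-PTBP1 and PTBP2 were compared within the Rosa-PTBP1 genotype, where both proteins can be present. On chromosome 15 from 30.1 to 30.2 Mb FLAG-PTBP1 held 67 sites against 1 of PTBP2, a share 48.3-fold higher (8.38 to 1937). On chromosome 1 from 77.4 to 77.5 Mb it held 34 against 1, 24.5-fold higher (4.11 to 997). On chromosome 13 from 46 to 46.1 Mb FLAG-PTBP1 held 40 sites and PTBP2 was listed at 0; this window was also named in the transgene comparison, which uses the same PTBP2 library. PTBP2 held the higher share on chromosome 17 from 86.8 to 86.9 Mb, with 14 sites against 6 (3.23-fold, 1.17 to 10.3), and on chromosome 1 from 125.5 to 125.6 Mb, with 16 against 8 (2.77-fold, 1.12 to 7.48). Of 446 windows on filled chromosomes, 242 were higher for FLAG-PTBP1 and 5 for PTBP2, with a Spearman correlation of 0.47 across windows. In the antibody simulation 6.57% of unchanged windows lay outside from counting error alone. The 5 windows higher for PTBP2 are therefore not shown to exceed such error. Of the PTBP2 Rosa-PTBP1 sites, 18.6% (18.1 to 19.1) overlapped a FLAG Rosa-PTBP1 site, against 4.28% for shifted sites; with the larger library thinned it was 10.4%. Of the stacked PTBP2 Rosa-PTBP1 sites on filled chromosomes, 68.4% (66.6 to 70.2) overlapped a stacked FLAG Rosa-PTBP1 site, against 14.6% for shifted sites. In the other direction, from the library with more stacked sites, it was 11.2% (10.7 to 11.7) against 2.44%. With all chromosomes, 341 windows were higher for FLAG-PTBP1 and 21 for PTBP2 from sites, and 387 and 133 from distinct intervals. Counts from distinct intervals put too many windows outside, since those of 1 site are not independent. The antibodies were sequenced in different runs, so antibody and run cannot be told apart here. The PTBP2 Rosa-PTBP1 library was also lower in most such windows against PTBP2 wild type (1 higher and 121 lower). Single-interval sites made up 46.2% of its sites, against 15.1% in FLAG Rosa-PTBP1. A trait of this 1 library therefore cannot be told apart from a difference between the proteins.

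Overlaps were also computed with the number of distinct intervals made equal, without wild-type FLAG replicate 2; the number of sites and the shifted level still differed between libraries. With 51141 intervals per library, 37.5% (36.7 to 38.4) of PTBP2 wild-type sites overlapped a FLAG Rosa-PTBP1 site and 23.1% (22.4 to 23.8) a PTBP2 Rosa-PTBP1 site. Over the shifted level these were 4.78-fold and 5.80-fold. The FLAG loxP library overlapped FLAG Rosa-PTBP1 at 46.1% (45.3 to 46.9), 4.84-fold over shifted sites, and wild-type FLAG replicate 1 did so at 3.15% (2.99 to 3.32), 1.88-fold.

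**Figure D4:**
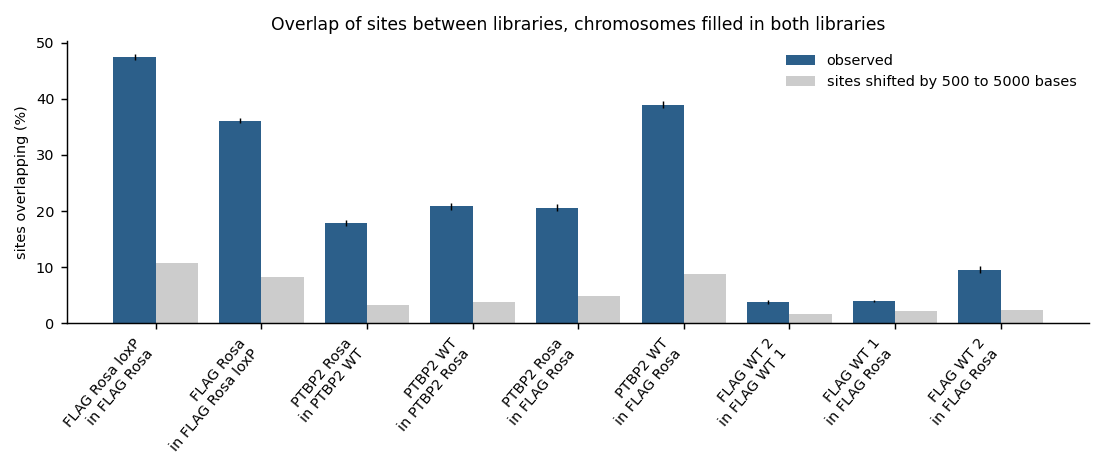
Blue bars show the percentage of the first library's sites that overlap a site of the second on chromosomes filled in both, with exact 95% intervals, and grey bars the same sites shifted by 500 to 5000 bases. The FLAG loxP library in FLAG Rosa-PTBP1 reaches 47.4%, and wild-type FLAG replicate 2 in replicate 1 reaches 3.82%.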

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

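The tests of line numbers and of empty chromosomes in this part were chosen after the results were seen. With the Rosa-PTBP1 transgene, stacked sites on the filled chromosomes moved in opposite directions for the antibodies: the log2 ratio of FLAG Rosa-PTBP1 was 6.004 over wild-type replicate 1 and 4.79 over replicate 2, and that of PTBP2 Rosa-PTBP1 over PTBP2 wild type was -1.21. These ratios are not scaled for depth, and distinct intervals ran the same way: 223107 in FLAG Rosa-PTBP1 against 51141 and 17129, and 61697 in PTBP2 Rosa-PTBP1 against 93916. The difference was not tested, and only the transgenic cortex carries the FLAG tag.

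FLAG wild-type replicate 1 listed about as many lines as FLAG Rosa-PTBP1 although it carries no FLAG-PTBP1. Reads crossing over from the PTBP2 libraries of the same runs were checked by identical intervals, and 0.318% of its distinct intervals were identical to an interval of either. Between the PTBP2 libraries themselves 1.24% of the wild-type intervals were identical. A crossed-over read need not leave an identical interval in its own library, so this check does not decide. Binding of the sites that the PTBP libraries list is argued against as the main content, since its sites overlapped FLAG Rosa-PTBP1 sites by 1.70 percentage points more than shifted sites, and its lines by 2.44. For its stacked sites, which hold 1.92% of its lines, such binding stays open: on filled chromosomes 17.5% overlapped a stacked FLAG Rosa-PTBP1 site against 4.63% for shifted sites (12.8 points more), and 16.6% a stacked PTBP2 wild-type site against 3.14%. Repeated lines of a sparse library remain a candidate explanation: it held 4.26 lines per distinct interval, against 1.06 in FLAG Rosa-PTBP1. Its lines per interval were 4.43 in run XA041 and 1.18 in run XB028. In XA041 PTBP2 wild type held 1.41 and PTBP2 Rosa-PTBP1 1.93. Its stacked sites numbered 1.66% of those of FLAG Rosa-PTBP1. That value is counted from distinct intervals, so it bears on how sparse the library is and not on the repeats.

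Chromosomes were nearly empty in 1 library each time. A loss of chromosome 10 binding in the Rosa-PTBP1 genotype is argued against for PTBP2, because the PTBP2 library of that genotype held 1.56 times the median chromosome 10 share of the other libraries. With 7 of its chromosomes sparse, its 13 filled chromosomes stood at 1.28 to 1.84, so this is an ordinary share for that library and not a gain. A loss on chromosomes 4 to 9 and X in that genotype is argued against for FLAG-PTBP1, whose lowest of the 7 ratios was 0.828. A candidate explanation is output missing from the deposited list: on chromosome 4 the ratio of PTBP2 Rosa-PTBP1 to wild-type sites fell at 60 Mb to 0.0635 of its earlier value. A loss of PTBP2 binding alone, beginning at a point on chromosome 4, was not tested. A loss of FLAG-PTBP1 binding alone on chromosome 10 was not tested either.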

How the results depend on the processing

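Alternatives on chromosomes filled in both libraries, sites of 5 or more intervals, single runs, distinct intervals as window counts, other library pairs, shares compared without an interval and other units for sites per library were added after the data were seen. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Gene-list and sequence alternatives were not run. On filled chromosomes and among stacked sites each overlap stayed above its shifted level. The 46 windows named by the rule in the loxP, transgene and antibody comparisons kept their direction under 184 alternatives in weight and pseudocount, of which 182 stayed within the main interval. The cause of the other shifts was not tested, except that thinning, a minimum of sites and filters remove sites by construction.

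The values follow in the order background (7.94%), wild-type replicates (3.84%), loxP (44.5%), transgene (17.6%) and antibody (18.6%). With 50% of the shorter site required they were 6.61%, 2.99%, 41.4%, 16.0% and 17.1%. Within 50 bases they were 12%, 5.93%, 51.0%, 20.2% and 21.2%. Among sites wider than the median the background was 6.52%, loxP 46.9%, transgene 22.6% and antibody 22.4%. Merged within 20 bases these were 8.30%, 43.1%, 16.5% and 17.7%. Without chromosome M and the 1% of windows with most sites the 5 values were 6.04%, 3.03%, 38.8%, 12.4% and 13.3%. With the larger library thinned they were 4.20%, 0.512%, 36.7%, 14.6% and 10.4%. On filled chromosomes loxP was 47.4% and antibody 20.6%. With both sides cut to sites of 5 or more intervals the background was 1.62%, loxP 55.0%, transgene 64.0% and antibody 62.6%. The background value was bound to fall, since the wild-type FLAG libraries hold only 402 and 857 such sites.

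Leaving out either wild-type FLAG library put the background between 1.98% and 6.38%. Using only sites outside wild-type FLAG sites gave 41.6% for loxP, 15.4% for the transgene and 16.1% for the antibody; with either wild-type library left out of that filter they lay between 42.1% and 43.8%, 15.8% and 16.9%, and 16.4% and 17.7%. The transgene overlap was 15.6% in run XA041 and 33.1% in run XB028. For the antibody comparison, PTBP2 wild type overlapped FLAG Rosa-PTBP1 at 36.7% and the loxP library at 34.3%.

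Windows outside the library-wide ratio numbered 147 for loxP, 231 with 10 or more sites, 57 with 50 or more and 576 from distinct intervals. For the transgene they numbered 118, 280, 35 and 230, and for the antibody 362, 612 and 133. Windows above both wild-type libraries numbered 335 of 562, 307 of 561 on filled chromosomes, 342 of 1101 with 10 or more sites and 405 of 562 from distinct intervals. The larger numbers from distinct intervals are not read as more differences, since distinct intervals of 1 site are not independent. Covered bases give no counting interval, so that count was not made from them; without an interval, 531 of the 562 windows had a higher share than in both by sites and 524 by covered bases. Above a single library there were 376 of 562 without replicate 1 and 493 of 1333 without replicate 2. FLAG wild-type replicate 1 over FLAG Rosa-PTBP1 was 1.71 for sites, 0.251 for distinct intervals, 1.01 for lines, 0.0166 for sites of 5 or more intervals and 1.16 for covered bases. Depth limits windows with few sites: a window of 20 sites cannot show small differences.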

Other observations

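The planned tests of displacement and gain were written before their results were seen; the choice of sites on 1 library alone, the XA041 value and the intervals of the correlations were added afterwards. Group medians are not scaled for depth, so only differences between groups are read. Overlap of sites is not evidence of competition or replacement, so 2 hypotheses were tested on sites with 10 or more distinct intervals, matched on the sum of intervals in the libraries compared.

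The first hypothesis was that FLAG-PTBP1 displaces PTBP2 at the sites it occupies. The log2 ratio of PTBP2 with over without Rosa-PTBP1 had a median of -0.97 at 2099 sites overlapping a stacked FLAG Rosa-PTBP1 site and -0.68 at 318 overlapping none (-1.50 and -1.28 in run XB028, 0.24 and 0.58 in run XA041); after matching on intervals, which weights the site heights differently, the difference was -1.01 (bootstrap 95% interval -1.95 to -0.53), which meets the criterion set in advance of at least 0.3 below with the interval below 0. It was -0.57 with the loxP library as the measure of occupancy, -0.47 within run XB028 and -0.51 within run XA041. With sites chosen and matched on PTBP2 wild type alone the medians were -1.37 and -2.87, lower at sites overlapping none, and the matched difference was 0.23 (-0.33 to 1.79), an interval that spans 0, so no difference in either direction was established with that choice; a choice on 1 library may favour sites that recur, and neither choice decides. A noisier PTBP2 library with Rosa-PTBP1 could also lower the ratio at shared sites, and the Spearman correlation between FLAG-PTBP1 intervals and the matched ratio across occupied sites, -0.109 (-0.1498 to -0.0687), lay between the range set in advance for a noisier library (-0.05 to 0.05) and the limit below which it would be argued against (-0.15). It was -0.08 (-0.13 to -0.03) in XB028. In XA041 it was -0.20, past that limit, but its interval (-0.27 to -0.14) reached above it, and with sites chosen on PTBP2 wild type alone it was -0.04 (-0.09 to 0.00), so displacement and a noisier library cannot be told apart here.

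The second hypothesis was that FLAG-PTBP1 gains at PTBP2 sites where PTBP2 is floxed. The matched difference between 4727 sites overlapping a stacked PTBP2 wild-type site and 7145 overlapping none was 0.179 on the log2 scale (0.10 to 0.27), below the 0.3 set in advance and above the 0.1 that would have argued against it. The group medians were -0.29 and -0.56. The difference was 0.12 (-0.01 to 0.22) with PTBP2 Rosa-PTBP1 as the measure, and 1.48 (1.36 to 1.64) with sites chosen and matched on FLAG Rosa-PTBP1 alone, a choice open to the same selection, so the hypothesis stays open.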
